A study of Mus musculus with 9 samples.

How the data were processed

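Messenger RNA of single cells was counted by inDrops in 9 mouse samples, 3 unsorted and 6 sorted, with 1 sample per group and 23 libraries in all. Libraries were made from Kit-enriched bone marrow or fetal liver cells, or from cells sorted on Kit, CD55, CD105, CD49f, CD150, CD41 and CD71 per the labels. The raw tables deposited by the authors hold UMI counts per gene and cell, in the unit counts, with a column that says whether a cell passed the authors' filter. The normalized tables of the unsorted samples deposited by the authors are in the unit signal. As tested on the files, each value there is the raw UMI count of a cell times 1 factor, so that the total without genes above 10% of any cell is equal in all cells of a table. The submitters' processing notes name Bowtie 1.1.1 and the genome GRCm38. The counting program, its version, the annotation release used for counting and the sequencing run of the sorted libraries are not given in the sources used here.

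All results use raw UMI counts of 28205 genes in cells that pass the authors' filter: 4763 of 5432 barcodes in basal marrow, 2611 of 2954 in Epo marrow, 7182 of 9482 in fetal liver, 3104 of 9640 in P1, 752 of 2537 in P1-CD71hi, 2435 of 3562 in P2, 2032 of 3944 in P3, 1210 of 2039 in P4 and 2460 of 3695 in P5. Basal library 1 came from run 1 and basal libraries 2 to 4 from run 4. Epo libraries came from run 2 and run 4, and fetal liver libraries from runs 3, 5, 5 and 6. Library totals ran from 1550243 UMIs (P1-CD71hi library 1) to 29156464 (fetal liver library 4). The precision this gave can be read from the erythroid share of basal marrow, 33.3% [31.9 to 34.6], and from folds such as 47.8 [26.5 to 96.2] for C2cd4a, a gene with few basal UMIs.

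Basal cells were scaled to the median total, log transformed and reduced to 50 principal components on 2000 variable genes (highest variance of log values above the running median for their mean, each gene scaled to unit variance, numpy 2.4.6). They were joined to 15 nearest neighbours (scikit-learn 1.9.0) and clustered by the Leiden method at resolution 1 with shared neighbour weights (leidenalg 0.10.2). Unnamed gene models, ribosomal and mitochondrial genes, Ptgfrn and genes that differed by more than 0.4 log2 in the same direction between the first and each other library of a sample (1860 genes in basal marrow, 3628 in Epo marrow, 5348 in fetal liver) were kept out of the variable genes, 15675 genes in all. Ptgfrn was kept out because it had 1.86 CPM in basal library 1 and 16812, 12392 and 10544 in basal libraries 2 to 4, 3.43 and 13500 in the Epo libraries, 51401, 10224, 8927 and 2354 in the fetal liver libraries and at most 1.95 in any sorted library. Epo cells and sorted cells took the class held by most of their 15 nearest basal cells, and fetal liver was clustered separately with the same settings, its variable genes centred within each library. When 20% of the basal cells were held out and placed in the same way, 90.6% of 914 cells got their class back (erythroid 99.6, neutrophil 98.8, monocyte 92.2, lymphoid 88.9, cluster 3 77.4, progenitor 75.3, dendritic 71.4 and basophil or mast cell 64.7% of 17).

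A cluster was named after a cell type if at least 3 of its markers, each seen in at least 10% of the cells, were raised by a log2 ratio of 1 or more against all other cells, with a margin of at least 2 markers over the next type and no other type with more markers among its leading 10 genes. A cluster with a median total under 1/3 of the sample median also needed a marker among those genes. In fetal liver a marker was raised against the other fetal liver clusters or against the mean of the basal clusters, and genes raised in at least 75% of the clusters were left out. The markers, resolution and numbers of genes, components and neighbours were fixed before the data were examined, while these naming thresholds, the filter on genes that differ between libraries and the centring of fetal liver were set afterwards. The basal clusters were defined by Mt2, Atp1b2, Car1 and Sphk1 (cluster 1, erythroid), Flt3, Dntt, Gcnt2 and Mpl (2, multipotent progenitor), Pf4, Apoe, Itga2b and Ifitm1 (3, unnamed), Ak4, Serpine2, Ctsg and Gstm1 (4, neutrophil), Sec14l2, Cldn13, Tmem56 and Rhd (5, erythroid), Mgl2, Vcam1, Gfi1 and Elane (6, neutrophil), Ly86, Irf8, Csf1r and F13a1 (7, monocyte), Ltf, Lcn2, Chil3 and Ly6g (8, neutrophil), Fcnb, S100a9, Gsn and S100a8 (9, neutrophil), Slc4a1, Hbb-bs and Gypa (10, erythroid), Igll1, Vpreb3 and Vpreb1 (11, lymphoid), Prss34, Mcpt8 and Cpa3 (12, basophil or mast cell), Tmcc2, Rsad2, Xpo7 and Hbb-bt (13, erythroid), Bpgm, Hbb-bt and Hba-a2 (14, erythroid) and H2-Aa, H2-Eb1 and Cd74 (15, dendritic). They held 832, 706, 515, 454, 454, 424, 408, 254, 166, 143, 117, 95, 84, 71 and 40 cells. Fetal liver clusters 1 to 4 were erythroid (Mt2, Arhgdig, Mt1, Cpox, Pklr and Mrap), 5 unnamed (Tgfbr3, Spns2, Apoe), 6 unnamed (Hmga2, Dnmt3b, Mycn, Ccr9), 7 neutrophil (Mpo, Prtn3), 8 hepatocyte (Serpina6, Apoa1, Apoa2), 9 megakaryocyte (Ppbp, Pf4), 10 unnamed (Ifitm1, Cpa3), 11 erythroid (Hbb-bh1, Hbb-bt) and 12 unnamed (Cdkn1c, Gap43, Sparc). They held 2073, 1111, 1080, 1034, 683, 543, 313, 112, 87, 87, 48 and 11 cells.

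Expression was compared on UMIs summed over the cells of a class or gate. Named genes had at least 50 CPM in at least 1 of the 2 samples, at least 50 UMIs in both together and no overlap between the library values of the 2 samples. Comparisons of erythroid-like cells were also made inside single clusters of the basal map, for fetal liver in clusters with at least 50 cells in both samples and after the pooled values were seen. Named genes were ranked by log2((CPM a + 10)/(CPM b + 10)), and the 12 highest and 12 lowest were named, or 8 and 8 for each pair of gates. Sorting antigens, animal sex genes and unnamed gene models were left out. The 14 marker lists and 19 other lists were fixed before the data were examined, and a list value is the median over members with at least 5 UMIs in both samples together. Its interval comes from 1000 redraws of the counts, and its percentile from 10000 random lists matched on mean expression in 20 bins. The genes Ddx3y, Eif2s3y, Kdm5d and Uty of the animal sex list summed to 134.8 CPM in basal marrow, 109.9 in Epo marrow, 50.4 in fetal liver, 104.3 in P1, 122.2 in P1-CD71hi, 87.4 in P2, 107.4 in P3, 69.1 in P4 and 80.1 in P5, and Xist is absent from the tables. No test was made in any comparison, because each group had 1 sample.

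Cell cycle shares per cell were taken after thinning to 1000 UMIs per cell. Links between classes were counted on the neighbour graph and set against the number expected from the sizes of both classes. Doublets were scored per library with the Scrublet method in scanpy 1.11.5, and doublet scores were not used to remove cells in the values of the report. The automatic threshold marked 42 of 14556 unsorted cells (0.289%) and 647 of 752 P1-CD71hi cells (86.0%), so it was not used, and the cells with the top 5% of scores in each library were left out as an alternative.

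The steps were tested on simulated data made from the real counts, with 200 genes changed by 1.5, 2, 4 or 8 times in each of the 7 comparisons. All libraries of a simulated sample were drawn from the same profile, so they differed by counting error only, unlike real libraries. At 2 times, 98% of changed genes had libraries apart in the right direction for Epo erythroid-like cells (22958 genes), 84% for Epo progenitor-like cells (17260), 100% for fetal liver (26993), 98% for P1 against P2 (20713), 100% for P1-CD71hi against P1 (20143), 98% for P3 against P5 (20543) and 100% for P4 against P5 (20906). At 1.5 times these were 98, 68, 98, 100, 100, 98 and 94%. All named genes were changed ones (24 of 24 or 16 of 16). Genes changed by 8 times were numerous enough to fill these places, so this count says little about named genes with smaller ratios. The largest absolute log2 ratio of an unchanged gene above the floors was 1.43 for progenitor-like cells and 0.29 to 0.45 elsewhere. Random lists of 18 members (20 lists) were drawn from the real comparison of Epo against basal erythroid-like cells (17766 genes), not from simulated counts. Their median percentile was 26.85 (0.25 to 97.75) when members were drawn by basal CPM and 44.9 (3.6 to 98.9) by the mean of both samples. Real differences between the samples remain in these percentiles. A list raised by 1 reached percentile 100 either way.

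The alternatives were cells of at least 2000 UMIs, resolution 2, marker scores instead of clusters, a joint map of Epo and basal cells, fetal liver placed on the basal map, 30 neighbours, no cell cycle genes among the variable genes, unthinned cells, median of ratios size factors, globins and mitochondrial genes out of the total, a pseudocount of 1, no minimum of UMIs for list members, means over cells, equal weight per erythroid cluster, the normalized tables and each library left out in turn, all chosen before the data were examined. Those chosen afterwards were the top 5% of doublet scores out, no filter on genes that differ between libraries, run 4 alone, joint classes for expression, cells with at least 10 UMIs of 6 granule genes out, and matching of the normalized tables by profile. That matching was needed because 9 of 2611 rows of the Epo normalized table carry the label of the raw profile they match. By profile 2507 rows matched cells that pass the filter, among them 1414 of the 1490 erythroid-like cells, and all rows matched in basal marrow and fetal liver.

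Gene positions are those of the RefSeq annotation on GRCm38, where Fam132a, Sdpr, Tmem56 and Tmem8 are called C1qtnf12, Cavin2, Tlcd4 and Pgap6. Python 3.11.15, scipy 1.17.1, pandas 2.3.3 and matplotlib 3.10.9 were used.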

Results

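Single-cell RNA counts from mouse blood progenitors were described in 9 samples, each the only sample of its group, so there were no replicates and no test was made. The 3 unsorted samples were Kit-enriched cells of basal bone marrow, of Epo-stimulated bone marrow and of embryonic day 13.5 fetal liver, and the 6 sorted samples were bone marrow gates called P1, P1-CD71hi, P2, P3, P4 and P5. All mice were BALB/cJ, and the bone marrow came from adults of 8 weeks by the sample labels. Libraries inside a sample are given as ranges and are not replicates.

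Cells passing the authors' filter numbered 4763 in basal marrow (18410673 UMIs, median 2989 per cell), 2611 in Epo marrow (9823489, median 3168) and 7182 in fetal liver (68732249, median 8858.5). In the gates they numbered 3104 in P1 (10982150, median 3339), 752 in P1-CD71hi (3511043, median 4739.5), 2435 in P2 (6909050, median 2712), 2032 in P3 (5028321, median 2139), 1210 in P4 (5496574, median 4640.5) and 2460 in P5 (4708023, median 1782.5). The series text states 5432, 2954 and 9482 cells for the unsorted samples, which equals all barcodes in those tables. For the gates the stated numbers equal the passing cells, out of 9640, 2537, 3562, 3944, 2039 and 3695 barcodes. Basal marrow had 4 libraries, Epo marrow 2, fetal liver 4, P1 4, P4 1 and each other gate 2. Intervals are 95% exact binomial for shares and exact Poisson for sums, and both cover counting error only, not differences between animals or preparations. Expression is given as CPM (UMIs of a gene scaled to an equal total), and list values are medians over members of log2((CPM a + 10)/(CPM b + 10)).

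The first question was which cell classes the basal Kit-enriched marrow held. Erythroid-like cells (basal clusters 1, 5, 10, 13 and 14) were the largest class at 33.3% [31.9 to 34.6] of 4763 cells, with libraries from 31.4 to 36.1%. Neutrophil-like cells (clusters 4, 6, 8 and 9) made up 27.3% [26.0 to 28.5], multipotent progenitor-like cells (cluster 2) 14.8% [13.8 to 15.9] and monocyte-like cells 8.57% [7.79 to 9.40]. Lymphoid-like cells held 2.46% [2.04 to 2.94], basophil or mast cell-like cells 1.99% [1.62 to 2.43] and dendritic-like cells 0.840% [0.601 to 1.14]. Cluster 3, 10.8% [9.94 to 11.7] of the cells, had raised markers of multipotent progenitors (9), megakaryocytes (5) and erythroid cells (4) together. It was left unnamed because another type had more markers than multipotent progenitors among its leading 10 genes. At a finer clustering 364 of its 515 cells fell in an unnamed cluster, 145 in a megakaryocyte-like cluster and 5 with progenitor-like cells. With cells of at least 2000 UMIs alone the progenitor share was 6.26% and the lymphoid share 1.31%. Naming each cell by marker score gave 9.71% progenitor-like and 3.61% basophil or mast cell-like cells.

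Which classes bordered each other in basal marrow was read from links between nearest neighbours, as observed over expected numbers. Basophil or mast cell-like cells were linked to cluster 3 at 1.02 [0.909 to 1.14] of the expected number (314 links) and to multipotent progenitor-like cells at 0.812, but to erythroid-like cells at 0.00633. Links share cells and are not independent counts, so that interval can be too narrow. Alternative settings gave 1.05 to 1.21 for the link to cluster 3. Monocyte-like cells were linked to multipotent progenitor-like cells at 0.922 and to neutrophil-like cells at 0.350. Cluster 3 was linked to multipotent progenitor-like cells at 0.520 and to erythroid cluster 1 at 0.498. Erythroid-like cells were linked to multipotent progenitor-like cells at 0.0162, while cluster 3 had links to both. Dendritic-like cells bordered monocyte-like cells (0.399), and lymphoid-like cells bordered multipotent progenitor-like cells (0.158). With the cells of the top 5% of doublet scores left out, the basophil to erythroid value was 0.00116.

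The next question was how the class shares of Epo-stimulated marrow compared with basal marrow. Erythroid-like cells were 57.1% [55.1 to 59.0] of 2611 Epo cells against 33.3% in basal marrow, a difference of 23.8 points [21.5 to 26.1] and a ratio of 1.72. Other classes were lower, neutrophil-like cells with a difference of -11.1 points (16.2% [14.8 to 17.7] against 27.3%), multipotent progenitor-like cells with -5.32 points (9.498% [8.40 to 10.7] against 14.8%) and monocyte-like cells with -2.59 points (5.97% [5.10 to 6.95] against 8.57%). Cluster 3 held 8.16% [7.14 to 9.27] of Epo cells, lymphoid-like cells 1.72% [1.26 to 2.30] and basophil or mast cell-like cells 1.38% [0.968 to 1.90]. No dendritic-like cell was seen among 2611 Epo cells, where 3 cells would have made 0.115%, against 0.840% in basal marrow. Inside the 1 sequencing run shared by both samples (run 4) erythroid-like cells were 55.9% against 33.5%, neutrophil-like cells 17.8% against 27.4%, progenitor-like cells 8.83% against 14.8%, cluster 3 8.13% against 10.4% and monocyte-like cells 6.49% against 8.67%. Within the erythroid-like class the earliest cluster (1) held 80.5% of Epo cells against 52.5% of basal cells, and cluster 5 held 6.58% against 28.7%. The later clusters 10, 13 and 14 held 7.32, 4.03 and 1.54% of Epo erythroid-like cells against 9.03, 5.30 and 4.48% in basal marrow. These are shares of a whole, so a higher erythroid share lowers the others. Naming by marker score moved the erythroid difference to 5.85 points, the progenitor difference to -0.343 and the monocyte difference to -0.719. Cells of at least 2000 UMIs gave a neutrophil difference of -18.0 and a monocyte difference of -4.55.

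**Figure D1:**
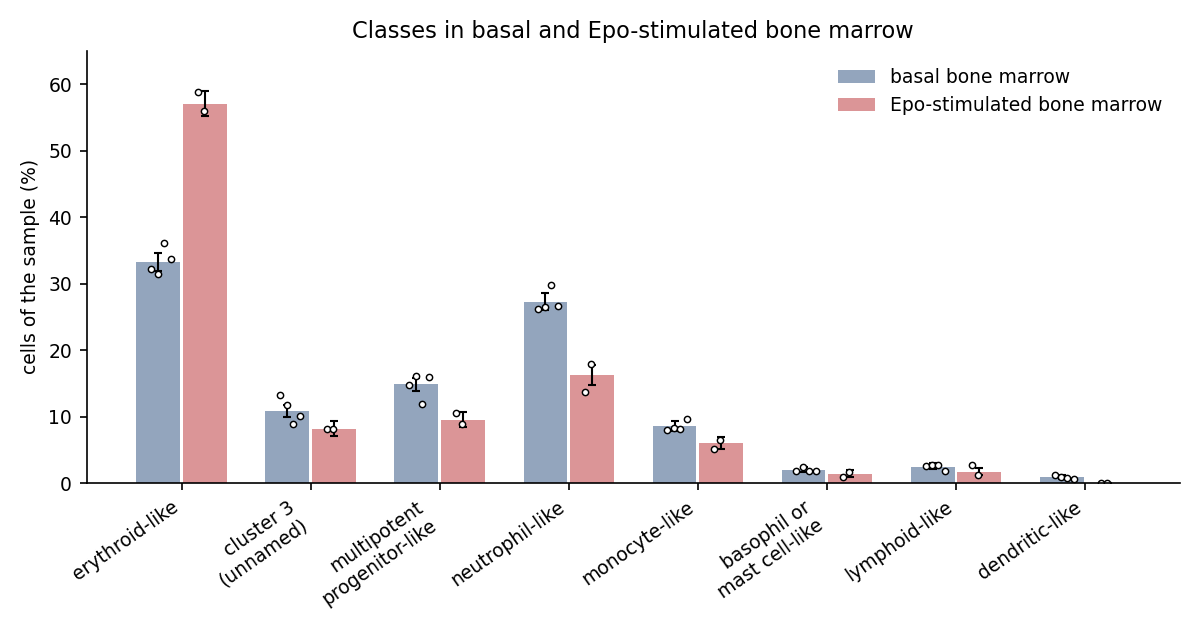
Share of cells (%) in each class for basal marrow and Epo marrow, with error bars showing exact binomial 95% intervals and circles the single libraries. Erythroid-like cells made up 33.3 and 57.1% of these samples.

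Fetal liver was compared with basal marrow for class shares by clustering it separately. Erythroid-like cells (fetal liver clusters 1 to 4 and 11) made up 74.4% [73.4 to 75.4] of 7182 cells, 41.2 points [39.5 to 42.9] above basal marrow and 2.24 times its share. Neutrophil-like cells were 4.36% [3.90 to 4.86], a difference of -22.9 points. Hepatocyte-like cells, which the marrow map lacked, were 1.56% [1.29 to 1.87] with libraries from 0.608 to 3.81%, and megakaryocyte-like cells were 1.21% [0.971 to 1.49]. The unnamed clusters 5, 6, 10 and 12 held 9.51, 7.56, 1.21 and 0.153% of fetal liver cells, 18.4% [17.5 to 19.4] together. Placed instead on the basal marrow map, 80.4% of fetal liver cells fell with erythroid-like, 7.85% with progenitor-like, 6.18% with cluster 3, 3.66% with monocyte-like and 1.42% with neutrophil-like cells. On that map 0.320% fell with basophil or mast cell-like, 0.125% with lymphoid-like and 0.0139% with dendritic-like cells. The 2 samples share no sequencing run and differ in age and tissue at once, so run and group cannot be told apart. Naming by marker score brought the erythroid difference to 4.46 points and clustering at resolution 2 brought it to 23.3 points.

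Where each sorted gate lay on the basal marrow map was asked by giving every sorted cell the class of its nearest basal cells. P1 and P1-CD71hi, gated as CD55+ CD105+ CD150- with CD71, were erythroid-like in 96.0% [95.3 to 96.7] and 98.8% [97.7 to 99.5] of cells. P2, the CD150+ CD71- gate, lay in cluster 3 in 79.2% [77.5 to 80.8] and in erythroid-like cells in 20.5% [18.9 to 22.1]. P3, gated as CD105- CD49f+ CD150- CD41-, held 60.9% [58.8 to 63.1] basophil or mast cell-like cells (libraries 60.7 and 61.1%), against 1.99% in unsorted marrow. The rest of P3 was cluster 3 (22.6%), progenitor-like (12.0%), monocyte-like (2.17%) and neutrophil-like (2.17%). P4, gated as CD150+ CD41+, lay in cluster 3 in 75.0%, in progenitor-like cells in 17.2% [15.1 to 19.4] and in basophil or mast cell-like cells in 5.04%. P5, CD150+ CD41-, lay in cluster 3 in 93.1% [92.01 to 94.06], in progenitor-like cells in 4.84% [4.02 to 5.76] and in erythroid-like cells in 0.610%. In P3 14.9% of cells took a class that less than 50% of their neighbours held, the highest value among the gates. Marker scores gave 62.7% erythroid-like cells in P1, 36.1% in P2 and 36.5% progenitor-like cells in P5, and P5 cells of at least 2000 UMIs gave 3.09% progenitor-like. Keeping genes that differ between basal libraries gave 41.8% erythroid-like cells in P2 and 8.84% progenitor-like cells in P4.

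**Figure D2:**
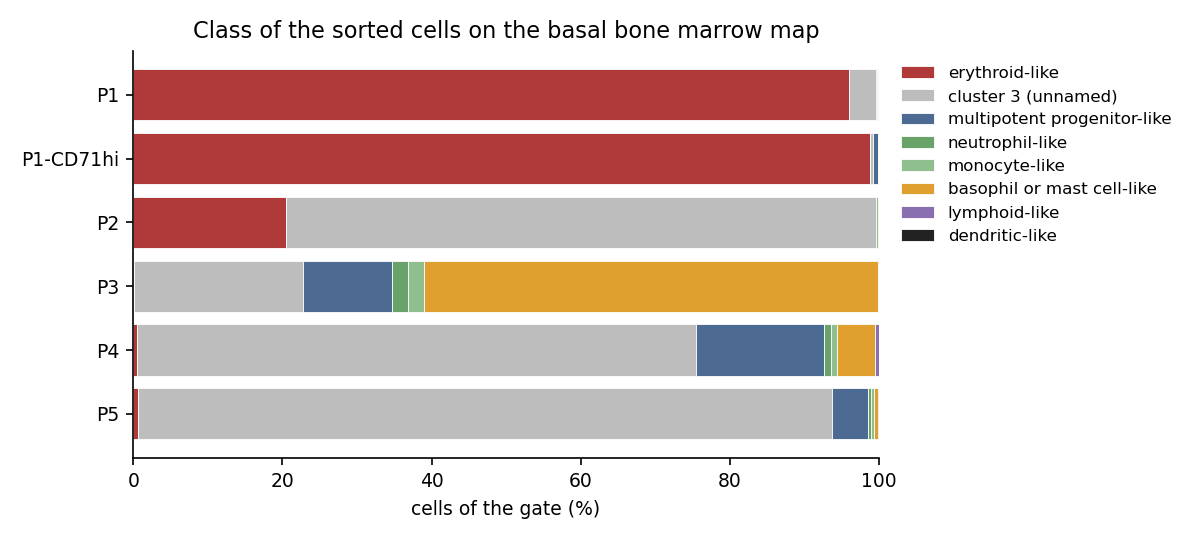
Share of cells (%) of the 6 sorted gates falling in each class of the basal marrow map, as stacked bars. Cluster 3 held 79.2, 75.0 and 93.1% of P2, P4 and P5, and P3 held 60.9% basophil or mast cell-like cells.

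Which genes differed in erythroid-like cells between Epo and basal marrow was read from pooled counts of 1490 and 1584 cells (6066426 and 5349655 UMIs, clusters 1, 5, 10, 13 and 14). Podxl, which encodes the sialomucin podocalyxin (chromosome 6, 31519493 to 31563937), had the largest log2 ratio, 3.74, at 191 CPM in Epo against 5.05 in basal cells, 37.9-fold [25.9 to 57.7]. C2cd4a (chromosome 9, 67830532 to 67832330) was at 98.2 against 2.06 CPM, 47.8-fold [26.5 to 96.2]. Cpd, a carboxypeptidase (chromosome 11, 76777208 to 76847008), was at 339 against 36.6 CPM, 9.26-fold [7.99 to 10.8], and the fatty acid binder Fabp5 (chromosome 3, 10012585 to 10016610) at 414 against 102 CPM, 4.05-fold [3.69 to 4.45]. Among the 12 highest genes stood also the protease gene Ctsc (109.9 against 9.72 CPM) and genes of neutrophil granules and of myeloid cells: S100a9 (375 against 32.7), S100a8 (223 against 19.8), Ngp (195 against 21.5), Ltf (73.2 against 4.49), Camp (85.4 against 7.48), Lyz2 (81.9 against 6.92) and Lcn2 (83.9 against 12.9). Epo library 1 carried much of the last group: without it S100a9 had 176 CPM, S100a8 80.1, Ltf 39.2, Camp 43.8 and Lyz2 28.2, and the log2 ratio of S100a8 was 1.60 (2.97 with both), of Camp 1.62 (2.45) and of Lyz2 1.18 (2.44). Without Epo library 2 S100a9 had 581 CPM, S100a8 371, Camp 128 and Lyz2 138, and without basal library 1 Lyz2 had 3.73 in basal cells.

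The 12 lowest genes in Epo erythroid-like cells began with the acyltransferase gene Mboat2 (chromosome 12, 24831435 to 24964400) at 10.7 against 53.6 CPM, 5.01 times lower, and Spon2 (chromosome 5, 33213518 to 33218254) at 16.2 against 65.2 CPM, 4.04 times lower. Pdcd4, an inhibitor of translation, was at 36.6 against 116 CPM, and Bpgm, whose enzyme makes the bisphosphoglycerate of red cells, at 72.9 against 181 CPM. The others were Cnp (52.4 against 149.7), Aldh1a1 (48.6 against 139), Atp8a1 (51.8 against 144), Arhgap23 (41.9 against 110.1), Gab1 (25.1 against 73.1), Agap1 (27.5 against 72.5), Ank (16.8 against 57.8) and Tmem8 (17.5 against 54.4). All 24 genes had the same direction inside run 4, but the rule of no overlap between library values fixed this in advance. Only the sizes carry information, with log2 ratios of 3.80 for Podxl, 3.15 for C2cd4a, 2.997 for Cpd, 1.93 for Fabp5, -1.69 for Mboat2 and -1.60 for Spon2. There S100a9 had 2.17 and S100a8 1.52. Without Epo library 2 Arhgap23 had 27.5 CPM and Bpgm 47.0 in Epo cells.

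The Epo and STAT5 response list was higher in Epo erythroid-like cells, with a median of 0.46 [0.35 to 0.55] and 16 of 18 members above 0 (0.44 inside run 4). Its members included the feedback inhibitor Cish (32.3 against 4.11 CPM), the cytokine Osm (43.8 against 7.48), the cyclin Ccnd2 (266 against 76.3) and Serpina3g (21.1 against 2.06). The receptor gene Epor was lower (123 against 179.5 CPM), as was the cyclin Ccnd3 (223 against 431). Glycolysis genes had a median of 0.52 [0.42 to 0.59] with 13 of 13 above 0 (0.56 inside run 4), led by Pkm (35.8 against 7.66 CPM), Pfkp (23.6 against 8.23) and Pgam1 (109.5 against 44.5). Cholesterol synthesis genes had 0.26 [0.15 to 0.35] with 14 above and 3 below (0.22 inside run 4), among them Fdps (37.7 against 17.4 CPM) and Idi1 (112 against 70.7). The early erythroid list was lower at -0.38 [-0.42 to -0.31], 13 of 16 below 0 (-0.29 inside run 4), with Sphk1 (139 against 292 CPM), Aqp1 (569 against 1152) and Car2 (2546 against 4532) below and the transcription factor gene Nfe2 (54.1 against 38.3) above. Among 10000 random lists matched on expression, the Epo and STAT5 list lay at percentile 100 and the early erythroid list at percentile 0, given as description.

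Haem synthesis genes had a median of -0.23 with 12 of 13 below 0 (-0.17 inside run 4), Uros at 79.3 against 135 CPM and Tmem14c at 608 against 972 CPM lowest. Adult globin and late erythroid genes had -0.12 with 10 of 12 below (-0.17 inside run 4), with Bpgm and Rhd (369.9 against 814 CPM) lowest. Without Epo library 2 these medians were -0.46 and -0.43, and without basal library 3 the late list had -0.21. The normalized tables gave -0.06 for haem synthesis, -0.69 for the late list, -0.04 for the early erythroid list and 0.47 for cholesterol synthesis. With every erythroid cluster weighted equally, early erythroid genes had -0.09, haem synthesis -0.02 and the late list 0.11, so the direction of the late list turned. A mean over cells put the late list at -0.53, and a pseudocount of 1 put the Epo and STAT5 list at 0.90.

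Taken cluster by cluster, the Epo and STAT5 list was above 0 in each erythroid cluster, at 0.42, 0.61, 1.40, 0.40 and 1.48 for clusters 1, 5, 10, 13 and 14. These medians rest on 18, 13, 11, 7 and 3 members, of which 16, 11, 9, 6 and 2 were above 0. In cluster 1 alone (1200 Epo and 832 basal cells) glycolysis genes had 0.38 with 12 of 13 above 0, and early erythroid genes -0.39 with 3 of 16 above. The early erythroid list had -0.30 in cluster 5 (6 of 16 above), -0.08 in cluster 10 (8 of 16 above), 0.61 in cluster 13 (10 of 14 above) and 0.34 in cluster 14 (2 of 4 above). In cluster 1 late erythroid genes had 0.00, haem synthesis -0.09, S phase genes 0.04 and ribosomal protein genes 0.15. In cluster 5 these lists had 0.30, 0.18, -0.04 and 0.25, in cluster 10 0.21, 0.01, -0.51 and 0.20, and in cluster 13 -0.03, 0.07, 0.92 and 1.68, where 65 of 65 ribosomal protein genes were above 0. All 24 named genes had the pooled direction in clusters 1 and 5, 22 had it in cluster 10 and 19 in cluster 13. Less than 50% of the pooled log2 ratio was kept by Bpgm in cluster 1 (-0.43 against -1.21 pooled) and by Bpgm (-0.28), Arhgap23 (-0.28) and Atp8a1 (-0.50) in cluster 5. Epo cells numbered 98, 109, 60 and 23 in clusters 5, 10, 13 and 14, against 454, 143, 84 and 71 basal cells.

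Markers of other cell types were measured beside these values. Neutrophil markers had 1.25 [1.16 to 1.39] in Epo erythroid-like cells, 15 of 16 above 0 (1.27 inside run 4), and monocyte markers 0.26 with 12 of 12 above (0.34 inside run 4). Without the cells holding at least 10 UMIs of 6 granule genes the neutrophil median was 0.09, and then Tmsb10 (148 against 33.5 CPM), Treml2 (50.7 against 6.95), Plac8 (145 against 37.0), Ccnd2 (272 against 76.5), Arpc1b (73.8 against 16.4), Gdf3 (140.0 against 37.6) and Lmo4 (84.3 against 25.6) entered the highest genes. That step kept the direction of 23 of the 24 named genes, and 17 kept at least 50% of their log2 ratio, the exceptions being S100a9, S100a8, Ngp, Ltf, Camp, Lyz2 and Lcn2. All of these but Lyz2 are the 6 genes by which the cells were picked, and these 6 are neutrophil markers. Their fall and that of the neutrophil median therefore follow in part from the step itself. With the top 5% of doublet scores out 24 kept direction and 19 kept that much, Ngp, Ltf, Camp, Lyz2 and Lcn2 falling short. The neutrophil median was 1.98 with a pseudocount of 1, 0.43 without the top doublet scores, 0.23 in the normalized tables and 0.58 with classes from a joint map.

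Of the other lists in Epo erythroid-like cells, S phase genes had -0.14 (10 above, 20 below, -0.12 inside run 4) and G2 and M phase genes -0.11 (8 above, 27 below, -0.13 inside run 4). Without Epo library 1 they had -0.09 and -0.05, without Epo library 2 -0.23 and -0.26, and without basal library 1 G2 and M phase genes had -0.18. Ribosomal protein genes had 0.19 but -0.08 inside run 4 and -0.31 without Epo library 1, and they had 0.59 without Epo library 2, 0.42 without basal library 1 and 0.12, 0.08 and 0.08 without basal libraries 2, 3 and 4. Mitochondrially encoded genes had 0.06 (-0.16 inside run 4). Erythroid markers had -0.36, iron handling -0.11, immediate early genes 0.16, interferon response -0.11, fetal and oncofetal genes 0.05, receptors -0.02 (0.08 inside run 4), sorting antigens -0.03, lineage antigens 0.51 (0.28 inside run 4) and transcription factors 0.11 (0.06 inside run 4). Multipotent progenitor markers had 0.09 (0.01 inside run 4), megakaryocyte -0.04, basophil or mast cell 0.09 (0.00 inside run 4), eosinophil 0.07, dendritic 0.13, lymphoid 0.05, T, NK and innate lymphoid 0.06, macrophage 0.00, hepatocyte -0.03, endothelial 0.01 (-0.03 inside run 4) and stromal 0.30 (0.09 inside run 4).

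**Figure D3:**
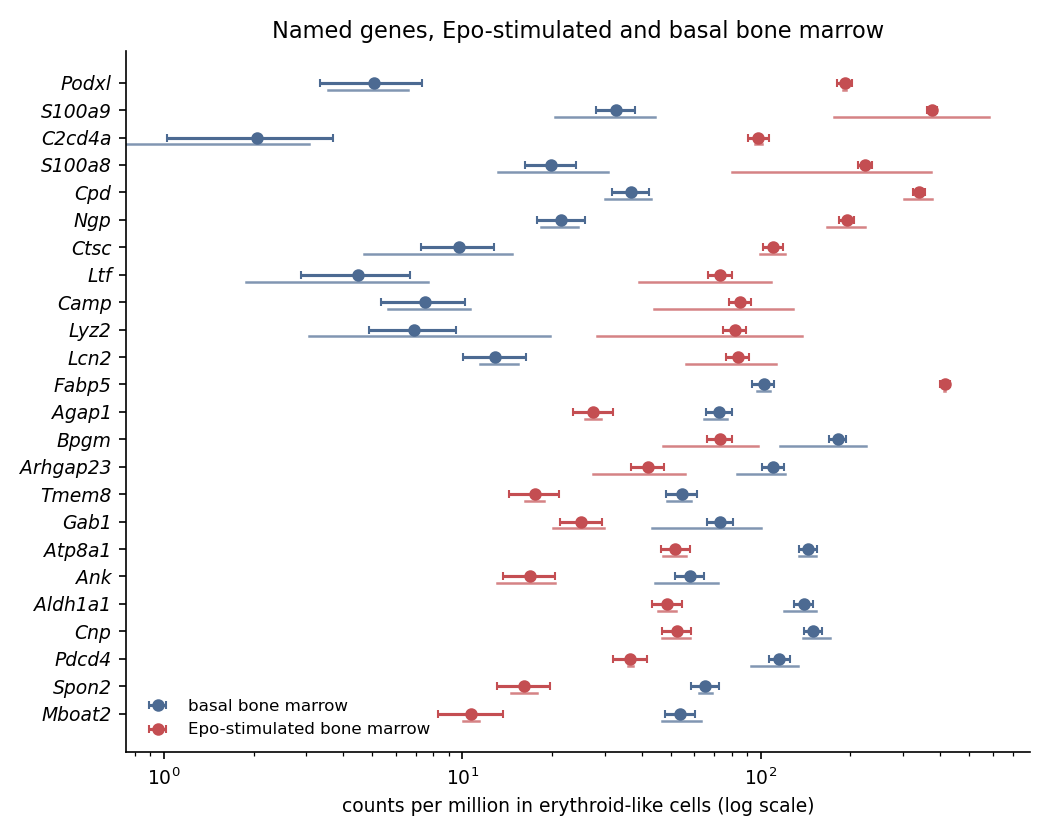
CPM on a log axis of the 12 highest and 12 lowest genes in erythroid-like cells of Epo and basal marrow, points with Poisson 95% intervals and thin lines for the range of libraries. Podxl lay at 191 against 5.05 CPM and Mboat2 at 10.7 against 53.6 CPM, and the C2cd4a line reaches the left edge since 1 basal library had none.

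Whether multipotent progenitor-like cells (basal cluster 2) also differed with Epo was asked with 248 Epo and 706 basal cells (342865 and 1274105 UMIs, medians 1159 and 1499.5 per cell). The macrophage-associated gene Wfdc17 (chromosome 11, 83704056 to 83706269) was highest at 181 against 33.7 CPM, 5.36-fold [3.57 to 8.10]. Next to it stood the lipoprotein gene Apoe (329.6 against 129 CPM), the lymphotoxin gene Ltb (157 against 54.2), Serpina3g (385 against 181; chromosome 12, 104236147 to 104241939), the chemokine Ccl4 (87.5 against 36.9) and the ETS factor Etv5 (61.2 against 25.1). Rpl37 (201 against 65.9), Gbp2b (78.7 against 28.3), Trim47 (78.7 against 29.8), Macrod1 (105 against 42.4), Aimp1 (108 against 45.5) and Mdfi (93.3 against 41.6) completed the highest 12. Among the lowest genes were Rrm2, a ribonucleotide reductase subunit (29.2 against 108 CPM; chromosome 12, 24708254 to 24714146), Bard1 (11.7 against 59.6), the checkpoint kinase Chek1 (11.7 against 50.2), the nucleoside kinase Dck (40.8 against 126), the mitotic kinase Pbk (23.3 against 77.7) and Shmt1 (20.4 against 77.7). Acp5 (chromosome 9, 22126727 to 22135746) had 0 UMIs in Epo cells, with an upper limit of 10.8 CPM, against 108 UMIs (84.8 CPM, libraries 3.59 to 272) in basal cells. The myeloid gene Ms4a3 (29.2 against 107.5), Sap30 (11.7 against 54.9), Arsb (11.7 against 53.4), Rgcc (14.6 against 53.4) and Cox15 (14.6 against 52.6) were the others. In simulated counts of this depth an unchanged gene reached an absolute log2 ratio of 1.43. The simulation held counting error only and no other differences between libraries, so real libraries can move a gene further. Beyond 1.43 lay Wfdc17, Rpl37, Acp5, Bard1, Ms4a3, Rrm2, Sap30, Arsb, Shmt1 and Chek1. The other 14 named genes, among them Ltb (1.38), Apoe (1.29) and Dck (-1.42), stayed inside that value. Without basal library 2 the basal level of Acp5 was 5.58 CPM. Single Epo libraries moved 6 of the other 23 by more than 1.5 times in log2 ratio. Without Epo library 1 Rpl37 had 0.98 (1.48 with both), Aimp1 0.47 (1.09), Mdfi 0.57 (1.002) and Bard1 -1.02 (-1.68), and without Epo library 2 Macrod1 had 0.56 (1.13), Etv5 0.64 (1.02) and Bard1 -2.80. Without Epo library 1 Sap30 had 18.2 and Chek1 6.07 CPM in Epo cells, and without Epo library 2 Sap30 had 5.61.

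The Epo and STAT5 list had a median of 0.19 [-0.08 to 0.47] in these cells, 10 above and 6 below 0 (0.22 inside run 4), against 0.46 in erythroid-like cells. Without basal library 2 it was 0.30. With no minimum of UMIs per gene it was 0.04, as a mean over cells 0.07 and without granule-high cells 0.10. S phase genes had -0.43 [-0.59 to -0.32] with 26 of 30 below 0 (-0.51 inside run 4), Tyms at 14.6 against 45.5 CPM, and G2 and M phase genes -0.44 [-0.62 to -0.30] with 30 of 35 below (-0.13 inside run 4), Tacc3 at 55.4 against 143 CPM and Cdk1 at 78.7 against 162 CPM. Multipotent progenitor markers had 0.43 [0.28 to 0.55] with 13 above and 3 below (0.35 inside run 4), Angpt1 at 166 against 79.3 CPM, Ifitm1 at 712 against 373 CPM and Mecom at 58.3 against 29.0 CPM. Interferon response genes had 0.45 [0.15 to 0.65] with 14 above and 3 below (0.33 inside run 4), Ifi44 at 26.2 against 11.0 CPM. Early erythroid genes had 0.39 [0.08 to 0.62] with 10 above and 3 below (0.26 inside run 4), Nfe2 at 143 against 83.2 CPM.

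Single libraries carried much of some of these values. Without Epo library 1 the median was -0.03 for G2 and M phase genes, -0.05 for ribosomal protein genes and 0.28 for progenitor markers. Without Epo library 2 it was -0.67 for S phase, -0.81 for G2 and M phase, 0.25 for interferon response and 0.85 for ribosomal protein genes, which had 0.45 with all libraries (0.25 inside run 4) and 0.79 without basal library 1. With classes from a joint map S phase had -0.06, G2 and M phase -0.12, interferon response 0.01 and progenitor markers -0.04, and a pseudocount of 1 put interferon response at 0.72. Neutrophil markers had -0.26, monocyte markers -0.30, haem synthesis -0.24 (-0.07 inside run 4), late erythroid genes 0.37 (0.18 inside run 4), glycolysis -0.07, cholesterol synthesis 0.13, immediate early genes 0.35 and iron handling 0.17. Stromal and endothelial markers had 0.87 and 0.68 on 6 members each.

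How fetal liver erythroid-like cells differed from basal marrow ones was read from 5346 and 1584 cells (54960613 and 5349655 UMIs, fetal liver clusters 1 to 4 and 11 against basal clusters 1, 5, 10, 13 and 14). The oncofetal RNA-binding protein gene Igf2bp1 (chromosome 11, 95957163 to 96005944) had the largest log2 ratio, 4.42, at 259 against 2.62 CPM, 99.0-fold [59.0 to 181]. The pyruvate kinase gene Pkm (chromosome 9, 59656576 to 59679372) was at 341 against 7.66 CPM, Lgals1 (chromosome 15, 78926725 to 78930465) at 1401 against 63.9, Gmpr (chromosome 13, 45507428 to 45546386) at 146 against 1.495 and the glucose transporter gene Slc2a1 at 64.97 against 1.12. The monocarboxylate carrier gene Slc16a3 (107 against 1.12 CPM), Pgam1 (487 against 44.5), Podxl (175 against 5.05), Fkbp1a (459 against 40.0), the desaturase gene Scd2 (989 against 133), Mrap (60.7 against 0.75) and the imprinted gene Snrpn (61.9 against 1.12) made up the rest of the highest 12. Basal levels near 0 moved with single libraries, Gmpr to 0.933, Slc16a3 to 0.7001 and Mrap to 0.467 CPM without basal library 1 and Slc2a1 to 0.528 CPM without basal library 2.

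Lowest in fetal liver was the carbonic anhydrase gene Car1 (chromosome 3, 14766214 to 14808365) at 20.2 against 1849 CPM, a log2 ratio of -5.94. Alas2, which encodes the erythroid enzyme that starts haem synthesis (chromosome X, 150547417 to 150570622), was at 34.9 against 514 CPM and the water channel gene Aqp1 at 86.7 against 1152. The exonuclease gene Isg20 (5.55 against 331 CPM), Lgals3bp (5.04 against 213), Lgals9 (57.0 against 867), the class I gene H2-D1 (39.2 against 552), Aldh1a1 (1.80 against 139), Paqr9 (3.93 against 148), Sdsl (2.11 against 112), Hpn (8.88 against 176) and Stard10 (22.4 against 307) were the other lowest genes. Without fetal liver library 1 Paqr9 had 2.40 CPM, Sdsl 0.216 and Hpn 3.80 in fetal liver, and without fetal liver library 4 Sdsl had 3.48. Their log2 ratios stayed between -3.75 and -3.18. All 24 named genes kept direction and at least 50% of their log2 ratio in each alternative that was run on the pooled classes.

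The fetal and oncofetal list had a median of 0.65 [0.59 to 0.82] with 16 of 17 above 0, Igf2bp3 at 66.7 against 1.87 CPM, Lin28b at 56.8 against 0.561 and Igf2 at 22.5 against 0.748. Glycolysis genes had 1.14 [0.96 to 1.19] with 12 of 13 above, Aldoa at 569 against 202 CPM, while Gapdh was below 0. Adult globin and late erythroid genes had -1.51 [-1.56 to -1.46] with 12 of 12 below in the pooled classes, which differ in stage mix as given next, Hbb-bt at 1738 against 12590 CPM and the anion exchanger gene Slc4a1 at 67.3 against 399.8. Early erythroid genes had -0.52 [-0.61 to -0.48] with 15 of 16 below, among them Car2 (1176 against 4532 CPM), and haem synthesis -0.29 with 9 of 13 below. Mitochondrially encoded genes had -0.80 with 12 of 13 below, and made up 2.41% of fetal liver erythroid UMIs against 4.50%. Globins made up 1.26% against 5.54% of the pooled UMIs. Cholesterol synthesis genes had 0.26 with 14 above and 3 below, and the Epo and STAT5 list 0.14 [0.08 to 0.20] with 12 above and 6 below, or 0.07 without fetal liver library 1.

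The mix of erythroid stages differed between the classes. On the basal map 79.4% of fetal liver erythroid-like cells lay in cluster 1 and 19.5% in cluster 5, against 52.5 and 28.7% of basal ones, while 0.580, 0.131 and 0.0561% lay in the globin-rich clusters 10, 13 and 14, against 9.03, 5.30 and 4.48%. Inside cluster 1 (4247 fetal liver and 832 basal cells) late erythroid genes were higher in fetal liver, at 0.64 with 10 of 12 above 0, and haem synthesis had 0.25 with 8 of 13 above. Inside cluster 5 (1045 and 454 cells) they had 0.80 and 0.30, so the direction of both lists turned. Globins there made up 3.29% of fetal liver against 0.477% of basal UMIs, and 0.269 against 0.0306% in cluster 1. Lists that kept their direction inside clusters 1 and 5 included the fetal list (0.76 and 0.69), glycolysis (0.90 and 0.67), early erythroid genes (-0.49 and -0.47), mitochondrially encoded genes (-1.02 and -0.74), cholesterol synthesis (0.10 and 0.24) and the Epo and STAT5 list (0.14 and 0.33). Of the named genes Alas2 alone lost its difference, at 9.57 against 12.6 CPM in cluster 1 and 63.9 against 44.2 CPM in cluster 5.

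Hepatocyte markers were higher in the fetal liver erythroid-like cells, at 0.41 with 11 of 12 above 0, Alb at 30.1 against 0.748 CPM and Afp at 37.7 against 0.935. Neutrophil markers were lower, at -0.90 with 15 of 16 below, Elane at 1.47 against 74.4 CPM and Mpo at 4.69 against 46.5. Erythroid markers had -1.37 in the pooled classes, endothelial 0.21, stromal 0.21, megakaryocyte 0.14, multipotent progenitor -0.02, basophil or mast cell 0.03, eosinophil -0.02, monocyte 0.05, dendritic -0.05, lymphoid 0.00, T, NK and innate lymphoid 0.09 and macrophage -0.13. Iron handling had -0.11, S phase 0.05, G2 and M phase -0.01, ribosomal protein genes 0.03, immediate early genes 0.07, receptors -0.03, transcription factors -0.03, sorting antigens 0.13 and lineage antigens 0.08. Interferon response had -0.10, or -0.21 without fetal liver library 1, -0.04 without fetal liver library 4 and -0.16 without basal library 1. A pseudocount of 1 gave 1.83 for the fetal list, 0.41 for cholesterol synthesis, 0.26 for the Epo and STAT5 list and -0.49 for interferon response. The normalized tables gave -3.27 for the late list, -0.51 for haem synthesis, 0.61 for cholesterol synthesis, -0.42 for mitochondrial genes and -0.25 for interferon response. Equal weight per cluster gave 0.62 for cholesterol synthesis, -0.09 for mitochondrial genes and -0.22 for interferon response. Means over cells gave -2.31 for the late list and -0.20 for interferon response. With globins and mitochondrial genes out of the total the Epo and STAT5 list had 0.09.

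**Figure D4:**
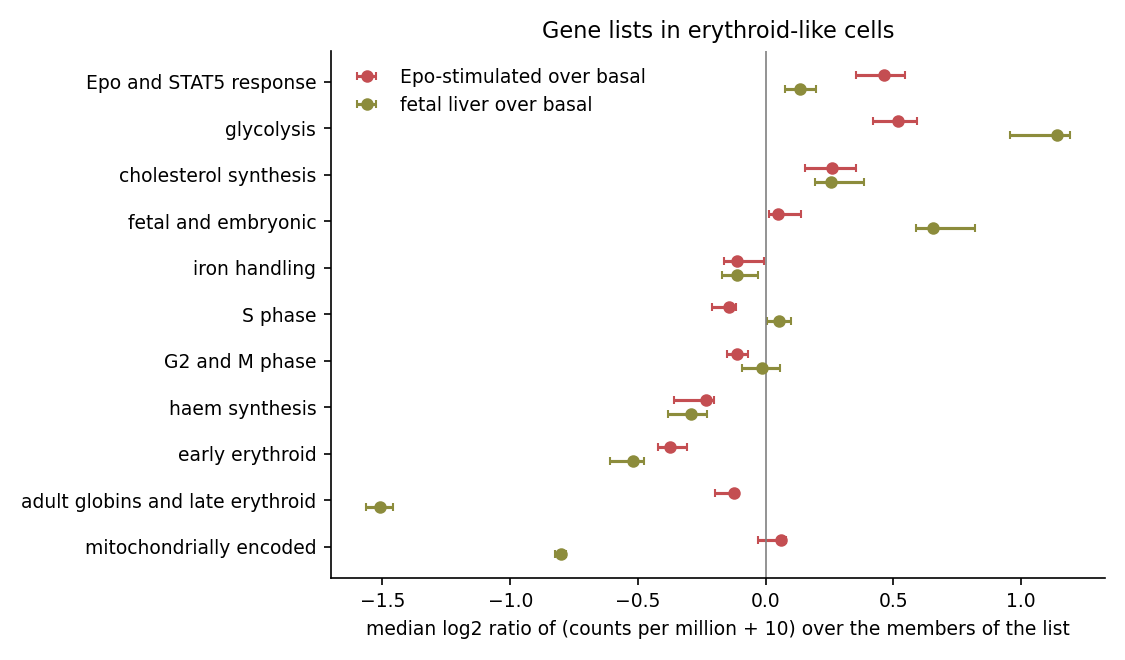
Median log2 ratio of each gene list in erythroid-like cells of Epo marrow and of fetal liver against basal marrow, with counting intervals. The Epo and STAT5 list lay at 0.46 and 0.14, glycolysis at 0.52 and 1.14, and late erythroid genes at -0.12 and -1.51, where the fetal liver class holds few cells of the late clusters and had 0.64 inside cluster 1.

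The gates were compared in pairs for genes that go with their surface markers, first P1 (CD71+) against P2 (CD150+ CD71-). Tmem56 (chromosome 3, 121202008 to 121283108) was at 102 CPM in P1 against 2.46 in P2, the spectrin gene Sptb (chromosome 12, 76580488 to 76710547) at 88.3 against 5.79 and the Rh antigen gene Rhd at 278 against 56.4. Fads3 (105 against 12.0), Spon2 (66.3 against 7.09), Nxpe2 (80.4 against 10.6), Cnn3 (97.5 against 15.5) and Mgll (55.6 against 6.08) were also higher. Vimentin, Vim (chromosome 2, 13574311 to 13582826), was at 7.92 in P1 against 251 in P2, with Plac8 (67.1 against 773; chromosome 5, 100551589 to 100572253), Apoe (81.3 against 752; chromosome 7, 19696244 to 19701310), the factor Gata2 (57.1 against 369.5), Ifitm1 (11.6 against 257), Lgals1 (222 against 1235), Gmfg (5.92 against 84.1) and Rab37 (4.10 against 66.7) lower as well. Early erythroid genes had a median of 0.31 [0.25 to 0.36] with 9 above and 7 below, Cldn13 (76.9 against 15.5), Car2 (1712 against 586) and Sphk1 (285 against 93.4) above. Haem synthesis had 0.66 (10 above, 3 below), with Fech at 157.5 against 66.9 and Tmem14c at 1115 against 521, and late erythroid genes 0.63 (12 of 12 above). S phase had 0.46 (28 of 30 above) with the cyclin Ccne1 at 219 against 46.9, and G2 and M phase 0.68 (35 of 35 above) with Plk1 at 203 against 56.0 and Cenpf at 427 against 154. Ribosomal protein genes had -0.28, mitochondrial genes 0.39, iron handling 0.35, glycolysis -0.41 with Pkm at 7.83 against 41.4, receptors -0.17, transcription factors -0.44 and megakaryocyte markers -0.22. Progenitor markers had -0.43 with 15 of 15 below, or -0.71 without P1 library 1, -0.67 without P2 library 2 and -1.32 with a pseudocount of 1.

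P1-CD71hi against P1 differed by the level of CD71. The haemogen gene Hemgn (chromosome 4, 46393989 to 46404183) was at 164 against 77.2 CPM, 2.12-fold, with the spectrin genes Spta1 (121 against 56.3) and Sptb (168 against 88.3), Tmem56 (202 against 102), Sec14l2 (53.8 against 24.3), Fam132a (109 against 55.9), Nudt4 (108 against 58.7) and the histone mRNA binder Slbp (383 against 223) also higher. Plac8 was at 9.11 against 67.1 CPM, 7.36 times lower, and Lgals1 (47.6 against 222), Arhgdib (8.54 against 62.6), Apoe (14.5 against 81.3), Ptprcap (27.9 against 120.2), S100a10 (14.0 against 69.4), Slc22a3 (14.2 against 51.8) and Rpl28 (1073 against 2418) were lower. Plac8 had 13.8 CPM without P1-CD71hi library 1 and 3.23 without library 2, where Arhgdib had 5.16 and the log2 ratio of Fam132a was 0.54 (0.85 with both). Haem synthesis genes had 0.31 [0.21 to 0.42] with 12 of 13 above 0, Uros at 71.5 against 40.2 and Slc25a38 at 99.7 against 62.2. Late erythroid genes had 0.29 (11 of 12 above), early erythroid 0.09 (11 of 16 above), S phase 0.31 (28 of 30 above), G2 and M phase 0.32 (33 of 35 above), ribosomal protein genes -0.33, iron handling 0.19, glycolysis -0.29 and basophil or mast cell markers -0.20.

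P3 against P5 differed by CD150. The granzyme gene Gzmb (chromosome 14, 56258836 to 56262334) was at 913 CPM in P3 against 1.27 in P5, 716-fold [329 to 1953], and the basophil protease Mcpt8 (chromosome 14, 56082163 to 56085499) at 483 against 12.1. The mast cell protease gene Cpa3 (2699.5 against 116), Prss34 (2588 against 100.0, or 212 without P5 library 1 and 13.6 without P5 library 2), the IgE receptor chain Ms4a2 (981 against 24.2), Jchain (2095 against 43.8, or 99.2 and 0.754 without those libraries), Cd53 (519 against 11.0) and Csf2rb2 (364 against 7.43) were higher as well. Lower in P3 were Slc14a1 (23.9 against 258; chromosome 18, 78100091 to 78142119), Car1 (198 against 1335), Aqp1 (67.4 against 483), Ces2g (23.3 against 157), Tnfaip2 (60.7 against 304), Ermap (8.95 against 72.4), Clec4d (35.996 against 187.6) and Samd14 (77.6 against 339.6). Basophil or mast cell markers had 3.98 [3.85 to 4.12] with 14 of 14 above 0, Fcer1a at 271 against 8.28. Eosinophil markers had 1.02 (6 of 7 above) with Prg2 at 426 against 62.4 and Epx at 120.5 against 19.7, or 2.75 with a pseudocount of 1. Neutrophil markers had 0.59 (9 above, 5 below) with Mpo at 655 against 65 and Ctsg at 974.5 against 119, monocyte markers 0.39 and T, NK and innate lymphoid markers 0.48. Early erythroid genes had -1.24 (16 of 16 below), megakaryocyte markers -0.66 (11 of 14 below), glycolysis 0.53, S phase -0.17 and G2 and M phase -0.34 (33 of 35 below).

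P4 against P5 differed by CD41, and P4 had 1 library. The platelet factor gene Pf4 (chromosome 5, 90772435 to 90773383) was at 622 CPM in P4 against 19.7 in P5, 31.5-fold, and the von Willebrand factor gene Vwf (chromosome 6, 125552948 to 125686679) at 79.0 against 6.16. Other megakaryocyte-lineage genes were higher, Itgb3 (56.4 against 2.76), Plek (259.8 against 39.9), Rap1b (649.7 against 123) and Sdpr (87.9 against 6.37), and so were Mcpt8 (109.7 against 12.1) and Ccl6 (52.0 against 2.55, or 3.89 without P5 library 1 and 1.51 without P5 library 2). Car1 was at 79.3 against 1335, 16.8 times lower, with Trib2 (28.7 against 337), Atp1b2 (6.37 against 85.4), Clec4d (29.1 against 187.6), Mst1r (4.18 against 61.2), Ugcg (64.8 against 349), Ctsl (18.9 against 127) and Rec114 (3.46 against 50.5) lower too. Megakaryocyte markers had 1.61 [1.46 to 1.72] with 16 of 16 above 0. Basophil or mast cell markers had 1.015 (12 of 14 above), or 1.79 with a pseudocount of 1 and 1.60 as a mean over cells. Prss34 was at 478.5 against 100.0, a P5 level that moved with single P5 libraries as given for P3 against P5. Progenitor markers had 0.66 (11 of 16 above) with Mpl at 330.4 against 95.8, eosinophil markers 0.71, S phase 0.42 (26 of 30 above) and G2 and M phase 0.79 (35 of 35 above), Aurkb at 157 against 61.6 and Ube2c at 427.5 against 179. Early erythroid genes had -0.59 (13 of 16 below) and glycolysis 0.34.

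The last question was how cell cycle genes differed along the erythroid clusters, ordered by late erythroid genes, which made up 0.118, 0.664, 29.4, 67.0 and 82.9% of UMIs in basal clusters 1, 5, 10, 13 and 14. S phase genes summed to 4863 CPM in basal multipotent progenitor-like cells, 4820 in cluster 3, 6760 [6665 to 6856] in erythroid cluster 1, 9809 in cluster 5, 10611 [10261 to 10969] in cluster 10, 339.6 in cluster 13 and 179 in cluster 14. G2 and M phase genes followed with 5073, 5786, 7772, 9651, 17719, 4666 and 1378. In Epo marrow S phase genes had 3628, 5237, 6926, 9376, 7615, 719 and 294 in the same order, and G2 and M phase genes 3675, 6663, 7616, 10198, 14584, 3561 and 836. With every cell thinned to 1000 UMIs, the log2 ratio of the S phase share in early erythroid clusters (under 10% late genes) to that in progenitor-like cells was 0.69 [0.63 to 0.75] in basal and 1.06 [0.93 to 1.19] in Epo marrow. The same ratio of late (over 50%) to early clusters was -4.51 [-4.96 to -4.09] and -3.75 [-4.24 to -3.31]. The higher early ratio in Epo marrow went with a lower S phase sum in progenitor-like cells (3628 against 4863 CPM). Sums in clusters 1 and 5 were close (6926 against 6760 and 9376 against 9809). With classes from a joint map, S and G2 and M phase genes of progenitor-like cells differed by a median of -0.07, against -0.43 here. The ratio is thus no sign of a steeper rise in Epo erythroid-like cells. Median S phase shares of thinned basal cells were 0.4% in progenitor-like cells (0.401% unthinned) and 1% in cluster 10 (1.05% unthinned). Cells too shallow to thin numbered 334 of 4763 in basal marrow (127 of them progenitor-like), 262 in Epo marrow (96 progenitor-like) and 0 in fetal liver.

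In fetal liver S phase genes had 5723 CPM in the unnamed cluster 5 and 6356, 7687, 6979, 7718 and 4355 in erythroid clusters 1, 2, 4, 3 and 11, and G2 and M phase genes 8521, 8935, 7778, 8886, 10465 and 9084. None of these fetal liver clusters reached the low S phase level of basal clusters 13 and 14, but none was as late either. Late erythroid genes held at most 41.2% of UMIs in them (cluster 11, 48 cells), against 67.0 and 82.9% in basal clusters 13 and 14. Among the gates S phase genes had 7457 CPM in P1-CD71hi, 5983 in P1, 4475 in P4, 4370.5 in P2, 3669 in P5 and 3262 in P3, and G2 and M phase genes 8721, 6906, 8137, 4200.0, 4837 and 3843. CPM sums depend on what else a cell makes, and globins take up most UMIs of clusters 13 and 14.

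**Figure D5:**
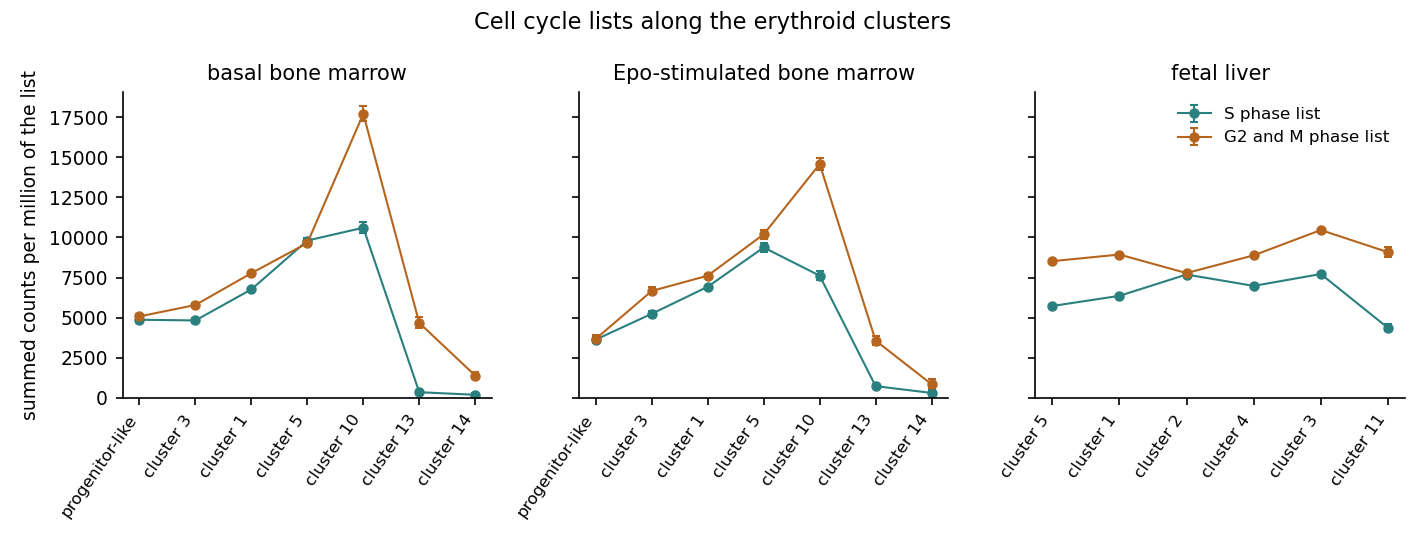
Summed CPM of S phase and of G2 and M phase genes per cluster, ordered along the erythroid clusters by late erythroid genes, with Poisson 95% intervals. Basal S phase genes went from 4863 CPM in progenitor-like cells to 10611 in cluster 10 and 179 in cluster 14.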

Additional observations from a re-analysis of the deposited data

Results flagged for a closer look

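Early erythroid genes went opposite ways in the 2 classes compared between Epo and basal marrow. Their median log2 ratio was -0.38 in erythroid-like cells and 0.39 in multipotent progenitor-like cells. The item stands here because the direction turned between classes in every pairing of an Epo with a basal library, from -0.54 to -0.07 in erythroid-like cells and from 0.07 to 0.68 in progenitor-like cells. The difference between the classes was not tested.

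Barcodes that the authors' filter left out hold reads that no result used. Mitochondrially encoded genes made up 9.45% of UMIs in the 669 left-out barcodes of basal marrow (4.23% in kept cells), 11.0% in 343 of Epo marrow (4.11%) and 12.3% in 2300 of fetal liver (2.42%). In the gates they made up 78.1% in 6536 left-out barcodes of P1 (10.7% in kept cells), 90.1% in 1785 of P1-CD71hi (9.83%), 63.3% in 1127 of P2 (8.50%), 36.1% in 1912 of P3 (5.56%), 78.4% in 829 of P4 (6.17%) and 52.4% in 1235 of P5 (6.54%). These values stand here because they describe unused data. The filter of the sorted tables itself has a mitochondrial criterion, so the values describe what it removed.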

How the results depend on the processing

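No paired analysis was possible because the labels pair no animal or sample of 1 group with one of another. Basal and Epo marrow share 1 sequencing run, which allows values within that run but no pairs to test, and no other grouping could be tested with 1 sample per group. Most settings were chosen before the data were examined. Leaving out the top 5% of doublet scores, dropping the filter on genes that differ between libraries, using run 4 alone, taking joint classes for expression and leaving out granule-high cells were chosen after the result was seen. Leaving out cells by the automatic doublet threshold was not run for any result. Across 67 results with 766 alternatives, 759 kept the sign, 567 stayed inside the counting interval and 192 moved outside it, and 7 turned the sign in 6 results. For the 16 results that answer a comparison, all 155 alternatives kept the sign, and 27 moved outside the interval. Both counts of kept signs include shares of cells and link ratios, which cannot be negative, so for those a kept sign carries no information.

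How cells were filtered and named moved the shares. Cells of at least 2000 UMIs gave 37.6% erythroid-like cells in basal marrow (33.3% with all), a difference of 27.9 points for Epo (23.8) and 36.7 points for fetal liver (41.2), and 63.4% basophil or mast cell-like cells in P3 (60.9). Marker scores gave 26.8%, 5.85 points, 4.46 points and 63.9% for the same values. Resolution 2 gave 31.6% erythroid-like cells in basal marrow, a fetal liver difference of 23.3 points and an S phase ratio of early erythroid to progenitor-like cells of 0.75 (0.69). Without the filter on genes that differ between libraries the basal erythroid share was 35.04% and the P3 basophil or mast cell share 66.3%. A joint map gave an Epo difference of 18.6 points. Placing fetal liver on the basal map gave a difference of 47.2 points. Leaving out the top 5% of doublet scores gave a fetal liver difference of 39.4 points and a link ratio of basophil or mast cell-like cells to cluster 3 of 1.21 (1.02), and 30 neighbours gave 1.14.

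How counts were scaled moved the lists. A pseudocount of 1 gave 0.90 for the Epo and STAT5 list in erythroid-like cells (0.46), 1.83 for the fetal list (0.65), 4.75 for basophil or mast cell markers in P3 against P5 (3.98) and 1.98 for megakaryocyte markers in P4 against P5 (1.61). The normalized tables gave 0.85 for the fetal list.

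With single libraries left out, the basal erythroid share ran from 32.4 to 34.2%, the Epo difference from 22.7 to 25.6 points, the fetal liver difference from 40.3 to 42.1 points and the P3 basophil or mast cell share from 60.7 to 61.1%. The Epo and STAT5 list ran from 0.43 to 0.50 in erythroid-like cells and from 0.15 (without basal library 1) to 0.30 (without basal library 2) in progenitor-like cells, where it was 0.19 with all. The fetal list ran from 0.63 to 0.75, early erythroid genes in P1 against P2 from 0.27 to 0.35, haem synthesis in P1-CD71hi against P1 from 0.27 to 0.33, basophil or mast cell markers in P3 against P5 from 3.68 (without P5 library 1) to 4.11, and megakaryocyte markers in P4 against P5 from 1.57 to 1.65. The S phase ratio of early erythroid to progenitor-like cells ran from 0.64 to 0.73 in basal marrow and from 0.79 (without Epo library 1) to 1.35 (without Epo library 2) in Epo marrow. The ratio of late to early clusters ran from -5.08 (without basal library 3) to -4.28 and from -3.80 to -3.71.

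The 7 turned signs among these 67 results were all in lists of Epo against basal cells. Lists outside that number, such as mitochondrially encoded genes and receptors, are not counted. In erythroid-like cells, equal weight per cluster gave 0.11 for late erythroid genes (-0.12), and the normalized tables gave 0.0655 for S phase genes (-0.14) and 0.0156 for G2 and M phase genes (-0.11). Ribosomal protein genes there had -0.0825 in run 4 alone and -0.31 without Epo library 1 (0.19 with all, from -0.31 to 0.59 over libraries). In progenitor-like cells ribosomal protein genes had -0.0458 without Epo library 1 (0.45 with all, from -0.05 to 0.85), and progenitor markers had -0.0367 with joint classes (0.43). The cause was not tested. For fetal liver, comparing cells of basal cluster 1 alone turned late erythroid genes from -1.51 to 0.64 and haem synthesis from -0.29 to 0.25. These values within clusters are not among the 766 alternatives.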

Other observations

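Single transcription factor and receptor genes, picked from the fixed lists after their values were seen, differed between the gates. Gata2 was highest in P3 at 2183 CPM, then 1136 in P5, 692 in P4, 369.5 in P2, 57.1 in P1 and 20.2 in P1-CD71hi, while the erythroid factor Klf1 had 532 in P1-CD71hi, 451 in P1, 357 in P2, 227 in P5, 75.4 in P3 and 58.8 in P4. Lmo4 had 3285 CPM in P3 against 169 in P5, Cebpa 285 in P3, and Pbx1 725 in P4 against 162 in P5. The thrombopoietin receptor gene Mpl had 330.4 CPM in P4, 95.8 in P5 and 21.9 in P3. Epor had 227 in P1, 210.5 in P1-CD71hi, 101 in P2, 94.9 in P5, 42.0 in P4 and 20.5 in P3. The receptor kinase genes Mst1r and Ryk were highest in the erythroid gates, Mst1r at 176, 161, 133, 46.5, 4.18 and 61.2 CPM and Ryk at 255, 194.0, 97.3, 20.5, 26.9 and 28.0 CPM in P1-CD71hi, P1, P2, P3, P4 and P5. Il17ra went the other way, at 190.1 in P5, 183 in P3, 161 in P2, 88.8 in P4, 65.4 in P1 and 55.3 in P1-CD71hi.

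Some genes, picked after their values were seen, differed between fetal liver clusters. Hmga2 had 896 CPM in the unnamed cluster 6, 17.2 in erythroid cluster 1 and 4.4 in erythroid cluster 3. The embryonic globin gene Hbb-bh1 had 657.5 CPM in cluster 11 against 37.2 in cluster 3, and Igf2bp1 had 18.9 CPM in cluster 11 against 181 to 302 in clusters 1 to 4. Alb had 954.7 CPM in the hepatocyte-like cluster and 26.7 to 113 in the others. In the unnamed cluster 10 the mast cell protease gene Cpa3 had 1817.5 CPM and Gata2 829.

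Neutrophil granule genes (Ltf, Ngp, Camp, S100a8, S100a9 and Lcn2) were higher in Epo than in basal erythroid-like cells, with a log2 ratio of UMIs per cell of 3.66. All tests of it were chosen after the pattern was seen, and what the test on the sequencing run should show was set only after the result was seen. Free RNA would reach every droplet alike, but progenitor-like cells had 0.0264 (-0.35 to 0.39) while cluster 3 had 4.27 (3.99 to 4.57), monocyte-like cells 2.61 and basophil or mast cell-like cells 2.26. Misplaced neutrophils would lack erythroid markers, but the granule-high cells had 62.1% of the level of the others, and the ratio inside run 4 was 2.61 (2.46 to 2.77), so free RNA added alike, misplacement and the run were argued against. Doublets remain possible and an own granule program stays open as untested, as 91.9% of the granule UMIs sat in cells with at least 10 of them, 46 of 1490 Epo cells (3.09%) against 6 of 1584 basal cells (0.379%), and 34.8% of the 46 cells had a top 5% doublet score against 5.47% of the others. However, the 46 cells had a median of 3185 UMIs, against 3593.5 in the other Epo erythroid-like cells and 3929 in Epo neutrophil-like cells. They thus lacked the higher total that 2 joined cells could give. The 6 basal cells had a median of 5027, against 3111 in the other basal erythroid-like cells.

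Of 76 genes with a log2 ratio of at least 1 with Epo and 134 with fetal liver, 17 were shared (2.47 if independent), and of 22 and 196 genes of at most -1, 14 were shared (1.05), and the tests that count genes were chosen only after the result was seen. With separate basal libraries at least 15 genes were higher in both (15 to 18), and in cluster 1 alone at least 16 (16 to 18, 2.08 if independent). For these genes this argued against counting error shared through the same basal cells and against a different mix of clusters. All basal libraries came from 1 sample, so a trait of that sample would stay in both comparisons. Stage inside cluster 1 was not equal either. Late erythroid genes held 0.290% of UMIs there in Epo against 0.118% in basal cells, and globins 0.269% in fetal liver against 0.0306%. Between 11 and 16 genes were lower in both, or 8 to 12 in cluster 1, for which no test was set. Podxl, Pkm, C2cd4a, Ctsc, Fabp5, Cpd, Pgam1, Arhgdig, Lmo4, Treml2, Arpc1b, Ydjc and Tspan14 were higher, and Aldh1a1, Col5a1, Cnp, Spon2, Mboat2, Pdcd4, Tmem8, Agap1 and Rhd lower, with either assignment of the basal libraries. Over all genes the covariance of the ratios was 0.0406 (0.00318 to 0.0781) with separate basal libraries and 0.0328 (-0.00766 to 0.0733) in cluster 1, against 0.0687 with all basal cells, so there the explanations cannot be told apart. A response to Epo shared by fetal liver and stimulated marrow is a biological difference that stays open as untested.

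S phase and G2 and M phase genes together were lower in Epo than in basal progenitor-like cells, at a median of -0.43 (-0.55 to -0.34, 65 genes). All tests of it were chosen only after the result was seen, with what each should show set before its value was known. Inside run 4 the median was -0.37 (-0.49 to -0.22), which argued against the run for both lists together and for S phase genes (-0.51), but G2 and M phase genes alone had -0.13 there and -0.03 without Epo library 1, so for them the run stays open. In cells of at least 1500 UMIs it was -0.26 (-0.44 to -0.20, 80 against 353 cells), which left shallower Epo cells undecided, and with classes from the joint map it was -0.0713 (-0.11 to -0.003, 464 against 1149 cells), so the projection possibly placed other cells in the class. Whether Epo lowered cycling of early progenitors stays open as untested.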
